A study of Mus musculus with 16 samples.

How the data were processed

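The series profiles dimethylation of histone H3 at lysine 4 (H3K4me2), a chromatin mark found at promoters and enhancers, in medullary thymic epithelial cells (mTEC) of C57BL/6 mice. The labels give 4 sorted populations with 2 H3K4me2 libraries each, and 8 further samples of whole-cell extract. The 8 H3K4me2 libraries were compared, and the whole-cell extracts are not analysed here. All populations were sorted as CD45-negative and Epcam-positive, with these further gates: mTEC-I, MHC class II low and Itgb4-positive; mTEC-II, MHC class II high; mTEC-III, Ly6D-positive; mTEC-IV, MHC class II low, Itgb4-negative and L1cam-positive. Per the labels' protocols, thymi were digested with enzymes, cells were enriched on a Percoll gradient, stained for flow cytometry and fixed with formaldehyde, and chromatin was precipitated with an anti-H3K4me2 antibody by a high-throughput form of ChIP derived from iChIP. The labels do not say whether replicates of a population came from separate mice, so the p-values measure only the spread between these samples, which may be technical.

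Per the submitters' processing notes, bcl2fastq 2.15.0.4 and Picard 1.108 were used and the genome build was mm9. The aligner, the handling of duplicate reads and the settings of the peak selection are not given in the sources used here. The merged table was made with HOMER's annotatePeaks program, per the file headers. It holds the H3K4me2 signal of each library in 29472 merged peaks, in tags per 10000000 tags of that library, as the authors deposited it. The deposited lists of peaks, 1 per population, are in HOMER's findPeaks format, with both replicates combined. In these lists the authors give each peak's signal per 10000000 tags, its fold over a control experiment and its p-value against that control. The lists carry the name of IDR, a measure of agreement between replicates, whose settings are not given in the sources used here. The fold and the p-value of a peak are the authors' own and were used only to describe, rank or filter peaks within a list.

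The header gives each library's total, so the deposited signal could be turned back into tags. In all 8 libraries 100% of values lay within 0.1 of a multiple of 0.5 tags, the step of the table. What a step of 0.5 tags stands for is not given in the sources used here. The library totals were 6461587 and 1702103.5 tags for mTEC-I, 15412132.5 and 13504742.5 for mTEC-II, 7926038.5 and 8492028 for mTEC-III, and 9093698 and 8369277 for mTEC-IV. A count of 0 allows a level of up to 3 tags, which is 4.64 and 17.6 tags per 10000000 in the mTEC-I libraries, 1.95 and 2.22 in mTEC-II, 3.78 and 3.53 in mTEC-III, and 3.30 and 3.58 in mTEC-IV. Such floors cover counting error only, since reads without molecular identifiers are not independent molecules.

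The test depended on the unit of the table, which was fixed in the design before the data were examined: edgeR for counts, or limma on a log scale for normalized values. The deposited values are normalized, so limma 3.58.1 (R 4.3.3) was used on log2(value + 1) with the trended variance (limma-trend), and count tests on the recovered steps of 0.5 tags are alternatives. Each step was taken as 1 count, so these tests used 2 counts per tag. A fold change on the log2(value + 1) scale understates the change of low peaks where depth is even. In mTEC-I replicate 2, where 1 tag is worth 5.88 tags per 10000000 and 1474 peaks stood at 0, it can also overstate a fall. Both mitochondrial peaks were left out, and peaks with at least 10 tags per 10000000 in at least 2 libraries were tested, which left 29469. Each peak was given to the gene of its nearest annotated start site, as the file annotates it. The values of all peaks of a gene were summed per library, which gave 15738 tested genes of 15739 annotated. A peak inside one gene can therefore count for a neighbour. Genes of families with near-identical copies (Ifit, Skint, Serpina3, Schlafen, Tas2r) are uncertain, because the sources used here do not say how reads shared between copies were counted. The fit held all 8 libraries, with 4 residual degrees of freedom and 7.75 prior degrees of freedom for peaks and 11.4 for genes. Each population was compared with the mean of the other 3, every pair was compared, and an F test asked whether the 4 populations differed. Benjamini-Hochberg adjusted p-values under 0.05 were called. Because the mean of the other 3 always holds 3 different populations, a gene far above the rest in 1 population is also lower in the contrasts of the others, and a gene far below the rest is also higher there.

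Gene lists, the rule for named genes, the comparisons and most alternatives were fixed before the data were examined. There were 22 lists: sort gate, basal and junctional epithelium, Aire-stage mTEC, MHC class II pathway, cornified epithelium, tuft cell, cortical thymic epithelium, pan-epithelial, thymocyte, fibroblast, endothelium, antigen-presenting haematopoietic cell, microfold cell, neuroendocrine cell, ciliated cell, muscle cell, gut and liver epithelium, interferon response, bitter taste receptor, proliferation, housekeeping and Y-linked. They hold 424 entries, of which 333 matched a gene of the table. Older symbols were matched through a RefSeq gene table of GRCm38.p6, used for names only. The table holds 0 peaks on the Y chromosome, so the Y-linked list gave no test. The other 21 lists were tested in each of the 4 populations with camera of limma, with its preset correlation of 0.01 and again with an estimated correlation, and p-values were adjusted over the 84 tests. No list of the 84 tests was called with an estimated correlation. Genes named in the report follow a fixed rule for each population: the 8 highest and 4 lowest changes among called genes above the median level with both libraries beyond the 6 others, all sort gate genes, and up to 4 genes of smallest p per list. The 2 higher peaks of smallest p were also named per population. Genes outside this rule are said to be chosen after their values were seen. Some results that the rule names are not reported here. The deposited peak lists were compared by overlap of at least 1 base after merging. Promoter peaks lay within 1 kb of an annotated start site.

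The fit was tested on simulated data with 200 changed peaks or genes per population, at the depths of the real libraries and a dispersion of 0.005. Of peaks changed 2-fold, 62% were recovered in mTEC-I, 66% in mTEC-II, 73% in mTEC-III and 58% in mTEC-IV, and of those changed 4-fold 96%, 97%, 92% and 94%. Of genes, 92%, 89%, 97% and 91% were recovered at 2-fold. The simulation gave 30 false peaks and 54 false genes in mTEC-I, 0 peaks in the other 3, and 0, 2 and 1 genes in mTEC-II, mTEC-III and mTEC-IV. With 200 true changes, the mTEC-I numbers are more than the threshold of 0.05 allows among calls. Only 200 peaks or genes were changed, while 17141 of 29469 tested peaks differed in the data, so these rates need not carry over.

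Alternatives were RLE size factors, equal totals in peaks, loess normalization, DESeq2 1.42.0 on the recovered steps of 0.5 tags, no filter, a replicate block, peaks within 20 kb of the start site, a promoter window of 3 kb, other overlap rules, and leaving out each library in turn. Leaving out a library leaves 1 in its population, and that lone sample is then assumed to vary like the other groups. Chosen after seeing the data were edgeR 4.0.16 and voom on the recovered steps of 0.5 tags, a pseudocount of 5 and a filter at 50. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Counted in whole tags, the mTEC-II libraries differed by no more than counting error over peaks (chi-square per degree of freedom 1, against 1.06 or more in the other pairs). Counted in steps of 0.5 tags it was 2, against 2.12 or more, so whether they differ beyond counting error depends on what such a step stands for. Their shares of mitochondrial tags were 0.0390% and 0.00604%, so they were kept as 2 libraries.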

Results

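H3K4me2 was measured in 8 libraries of sorted mouse medullary thymic epithelial cells, 2 from each of the populations mTEC-I, mTEC-II, mTEC-III and mTEC-IV, to profile the enhancer landscape of these cells. Medullary thymic epithelial cells display antigens of other tissues to developing T cells. The libraries held from 1702103.5 to 15412132.5 tags, and 31.9% to 35.4% of these lay in the merged peaks. The shallowest was mTEC-I replicate 2, where 1 tag is worth 5.88 tags per 10000000. Levels below are H3K4me2 tags per 10000000, as mean ± SD of n = 2 libraries. A gene's level is the sum over the peaks nearest to its start site. Changes are on the log2(value + 1) scale against the mean of the other 3 populations, ± SE, with limma's Benjamini-Hochberg adjusted p.

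Itgb4, Ly6d and L1cam, genes of the sort gates, carried most H3K4me2 in the population sorted for each. Itgb4, an integrin chain of the basal cell surface, stood at 308 ± 32 (SD, n = 2) in mTEC-I against 224 to 241 in the others (log2 change 0.41 ± 0.090 SE, adjusted p = 0.0022). Ly6d reached 333 ± 26 in mTEC-III against 76.5 to 106 (1.86 ± 0.15 SE, adjusted p = 5.0e-07), and L1cam, a cell adhesion molecule, 191 ± 13 in mTEC-IV against 47.6 to 67.8 (1.72 ± 0.18 SE, adjusted p = 1.8e-06). H2-Aa and H2-Ab1, which encode an MHC class II molecule, were lower in mTEC-IV (-0.72 and -0.61, adjusted p = 3.7e-06 and 3.3e-06). In the MHC class II high population mTEC-II they stood at 402 ± 5.8 and 628 ± 30.0, but H2-Aa was also high in mTEC-I, at 444 ± 17 (0.45, adjusted p = 5.0e-04), a population sorted as MHC class II low. Epcam was higher in mTEC-IV (0.34, adjusted p = 5.2e-04) and lower in mTEC-I (-0.22, adjusted p = 0.0134), 2 calls that ended when only peaks within 20 kb of the start site were used (0.11, adjusted p = 0.314, and -0.042, adjusted p = 0.701). Ptprc encodes CD45, the marker that all 4 sorts excluded, and it was higher in mTEC-IV, at 267 ± 3.4 against 32.0 to 43.9 (2.84 ± 0.18 SE, adjusted p = 4.9e-09).

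Gate genes were also called in other populations, and several of these calls changed with a library or with the processing. Ptprc was lower in mTEC-I (-1.04), mTEC-II (-0.61) and mTEC-III (-1.19), each against a mean that holds mTEC-IV, and the mTEC-II and mTEC-III calls ended within 20 kb of the start site (-0.83, adjusted p = 0.362, and -0.48, adjusted p = 0.606). The Ptprc call in mTEC-II (adjusted p = 0.0240) also ended without either mTEC-II library (-0.45 and -0.77, adjusted p = 0.372 and 0.0993) and without either mTEC-IV library (-0.60 and -0.61, adjusted p = 0.0792 and 0.0756). In mTEC-II, H2-Ab1 (0.34, adjusted p = 0.0023) ended without mTEC-II replicate 2 (0.29, adjusted p = 0.111). H2-Aa (0.25, adjusted p = 0.0365) ended without mTEC-II replicate 1 (0.310) or 2 (0.231), without mTEC-III replicate 1 (0.0657) and without mTEC-IV replicate 1 (0.0735) or 2 (0.0730), with changes of 0.24, 0.27, 0.21, 0.25 and 0.26. Ly6d was lower in mTEC-II (-0.96, adjusted p = 4.2e-04) and in mTEC-I (-0.57, adjusted p = 0.0078), the latter not without mTEC-I replicate 2 (-0.29, adjusted p = 0.125) or with voom (0.0781). L1cam was lower in mTEC-III (-0.93, adjusted p = 9.8e-04). It was not past the threshold in mTEC-I (-0.30, adjusted p = 0.221) or mTEC-II (-0.49, adjusted p = 0.0659), but passed in mTEC-I without mTEC-I replicate 2 (0.0104) and in mTEC-II without either mTEC-I library (0.0012 and 0.0365), with edgeR (0.0469) and with voom (0.0447). Epcam in mTEC-II (-0.18, adjusted p = 0.0597) passed without mTEC-I replicate 1 (0.0144) or 2 (0.0231) and without mTEC-III replicate 1 (0.0102). It also passed with peaks within 20 kb of the start site (-0.31, adjusted p = 0.0097), as did Epcam in mTEC-III (0.24, adjusted p = 0.0236), which did not pass with all peaks (0.056). H2-Ab1 in mTEC-I (0.14), H2-Aa and H2-Ab1 in mTEC-III (0.019 and 0.13) and Itgb4 in mTEC-II (-0.049) did not pass. Itgb4 in mTEC-III (-0.18) and mTEC-IV (-0.18) and Ly6d in mTEC-IV (-0.33) did not pass either, but did without mTEC-I replicate 2 (adjusted p = 0.0347, 0.0305 and 0.0023) and with edgeR (0.0450, 0.0364 and 0.0040). In mTEC-IV both also passed with equal totals in peaks (0.0230 for Itgb4 and 0.0320 for Ly6d) and with voom (0.0018 and 4.1e-04), and Ly6d with DESeq2 (0.0157). As a list, the gate genes were not called in any population (camera adjusted p = 0.841, 0.758, 0.921 and 0.921 for mTEC-I to mTEC-IV), with 2, 2, 1 and 3 of 7 genes higher and 3, 2, 2 and 2 lower. Adjusted over the list alone, 2, 2, 1 and 3 were higher and 3, 4, 2 and 3 lower.

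**Figure D1:**
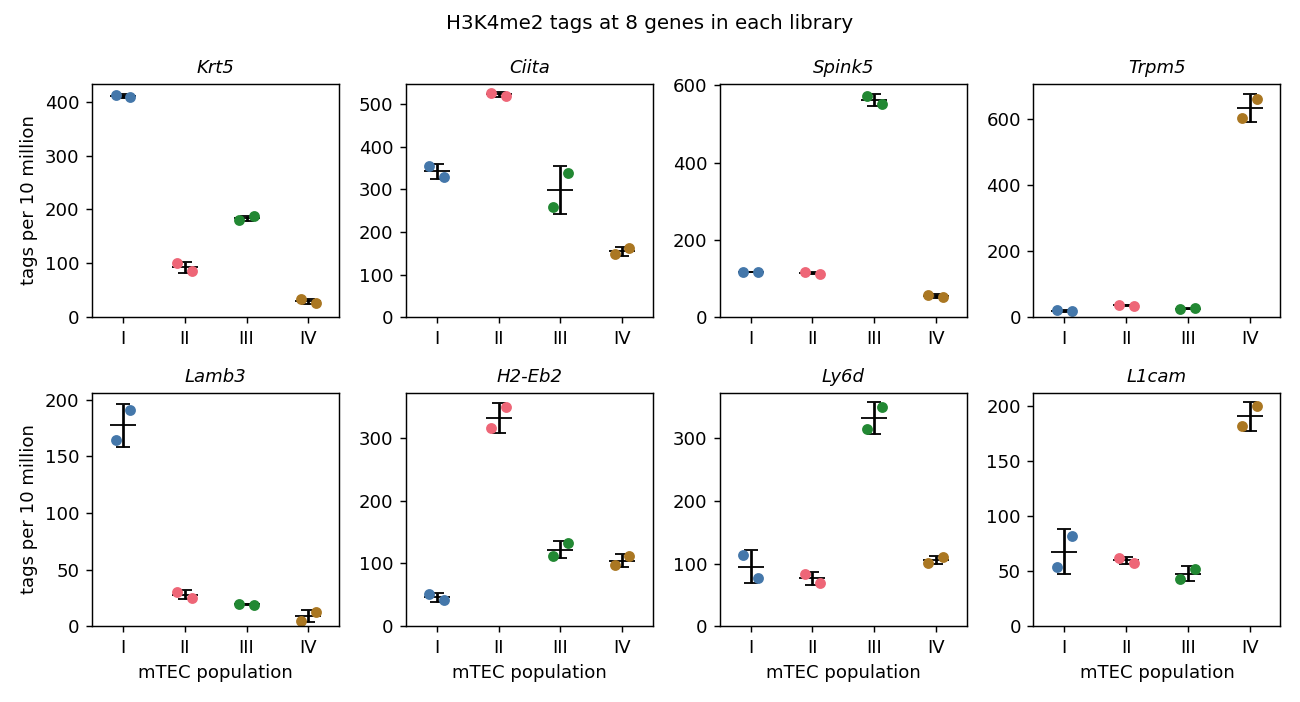
H3K4me2 level of 8 genes in each library, in tags per 10000000, with 1 point per library and the mean ± SD of each mTEC population (n = 2). Krt5 and Lamb3 were highest in mTEC-I (411 and 178), Ciita and H2-Eb2 in mTEC-II (523 and 332), Spink5 and Ly6d in mTEC-III (562 and 333), and Trpm5 and L1cam in mTEC-IV (632 and 191).

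The 4 populations differed at 17141 of 29469 tested peaks (58.2%, F test) and at 8528 of 15738 genes (54.2%). mTEC-IV stood apart from the rest. Its libraries correlated with those of the other populations at 0.637 to 0.707 over peaks (12 pairs), while mTEC-I, mTEC-II and mTEC-III correlated with each other at 0.815 to 0.903 (12 pairs) and libraries of the same population at 0.916 to 0.984 (4 pairs). These are correlations across peaks, which are not independent replicates. The first principal component held 55.2% of the variance and placed the mTEC-IV libraries at 144 and 147 and the other 6 between -129 and -18.9. The second held 22.8%, with the mTEC-I libraries at 40.2 and 101, those of mTEC-IV at 38.5 and 42.5, and those of mTEC-II and mTEC-III between -64.3 and -46.8. Called higher and lower than the mean of the other 3 were 4338 and 6814 peaks in mTEC-I, 3015 and 2130 in mTEC-II, 3338 and 4173 in mTEC-III, and 6929 and 4223 in mTEC-IV. The order depended on the processing: with loess, edgeR and voom mTEC-IV had the most lower peaks (5542, 6623 and 7760, against 5171, 6383 and 5049 in mTEC-I). With loess mTEC-IV and mTEC-I had nearly as many higher peaks (4530 and 4528). Without mTEC-IV replicate 1 or 2, mTEC-I had the most higher peaks, 3466 and 3620 against 3465 and 3144.

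**Figure D2:**
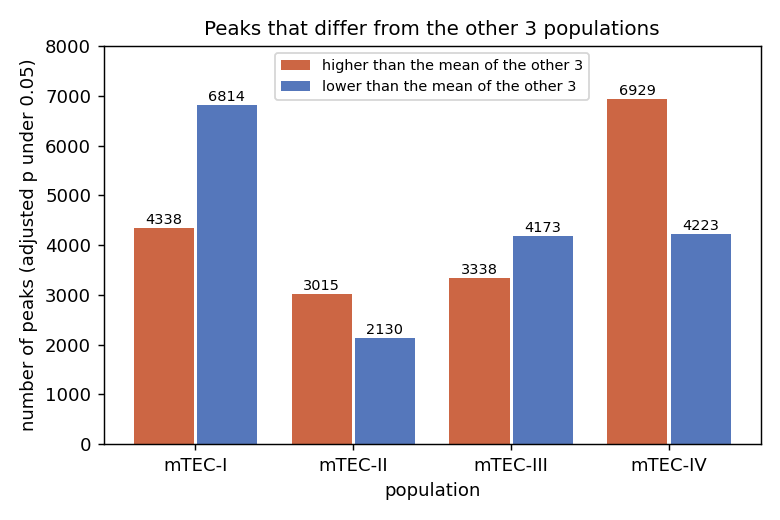
Number of peaks higher (orange) and lower (blue) in each mTEC population than in the mean of the other 3, at an adjusted p under 0.05. As plotted, mTEC-IV had the most higher peaks, 6929, and mTEC-I the most lower peaks, 6814, an order that changed with loess, edgeR and voom.

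In mTEC-I, genes of basal epithelium carried more H3K4me2 than in the other populations. Krt5, a keratin of basal cells, stood at 411 ± 3.5 (SD, n = 2) against 29.6 to 184 (2.35 ± 0.13 SE, adjusted p = 7.0e-09). Lamb3, a chain of the basement membrane protein laminin-332, stood at 178 ± 19 against 8.75 to 27.8 (3.36 ± 0.30 SE, adjusted p = 6.4e-07). The glycoprotein gene Pdpn (1.21) and the cytokine receptor gene Lifr (0.79) were also higher (adjusted p = 5.5e-07 and 1.4e-07). The basal and junctional list had 10 of 18 measured genes higher, 0 lower and 8 not called (10 and 0 adjusted over the list alone), with camera adjusted p = 2.8e-05, and adjusted p = 0.171 with an estimated correlation. The cortical epithelial list had 7 of 14 measured genes higher, 1 lower and 6 not called (8 and 1 adjusted over the list alone), with camera adjusted p = 0.0157, and adjusted p = 0.514 with an estimated correlation. Its higher genes included the T cell growth factor gene Il7 (1444 ± 27 against 811 to 890.3, 0.76), the chemokine genes Cxcl12 (0.78) and Ccl25 (0.63), and the protease gene Ctsl (0.71), with adjusted p = 1.4e-07, 5.1e-05, 8.5e-04 and 2.8e-05.

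Interferon-induced genes rose in mTEC-I as well. Ifit3 stood at 344 ± 13 against 20.6 to 58.9 (3.02 ± 0.16 SE, adjusted p = 4.8e-09), and Ifit2 (1.40), the antiviral gene Mx1 (1.64) and Oasl2 (0.68) rose too (adjusted p = 1.4e-07, 8.3e-07 and 2.8e-06). The list had 16 of 19 measured genes higher, 0 lower and 3 not called (17 and 0 adjusted over the list alone), with camera adjusted p = 5.7e-08, and adjusted p = 0.0578 with an estimated correlation. Its median was 0.54 without mTEC-I replicate 1 and 0.48 without replicate 2. The 2 higher peaks of smallest p belonged to such genes: a peak in intron 1 of Iigp1 (chromosome 18, 60532705 to 60539511, mm9; 663 ± 33, 2.15 ± 0.10 SE, adjusted p = 2.7e-07) and one in intron 1 of Ifit3 (chromosome 19, 34657099 to 34661281; 3.02 ± 0.15 SE, adjusted p = 2.7e-07). Collagen genes of the fibroblast list moved with them, Col6a1 by 1.58 and Col6a2 by 1.87, as did the proteoglycan gene Dcn by 2.15 (adjusted p = 6.1e-07, 3.9e-06 and 3.0e-05). That list had 8 of 13 measured genes higher, 3 lower and 2 not called (8 and 3 adjusted over the list alone), with camera adjusted p = 0.0861.

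The largest rises in mTEC-I by the fixed rule were at Mir205, a microRNA gene of epithelium (504 ± 52, 1.94), Serpina3i (1.79), 3110039I08Rik (1.73), Mill1, an MHC class I-like gene (1.71), Hoxaas2 (1.67), Iigp1, an interferon-inducible GTPase (1.61), Serpina3h (1.56) and Slfn8 of the Schlafen family (1.41). Their adjusted p-values lay between 1.8e-08 and 1.7e-07. Slfn8 was nearly as high in mTEC-IV, at 331 against 364 in mTEC-I and 84.5 and 91.4 in mTEC-II and mTEC-III. The largest falls were at the homeobox gene Hoxc11 (41.5 ± 0.47 against 236 to 343, -2.75 ± 0.099 SE, adjusted p = 1.1e-10), the intestinal regulator Cdx1 (-2.27), the transcription factor gene Fezf1 (-2.26) and the microRNA gene Mir10b (-2.16), with adjusted p = 1.6e-08, 2.3e-09 and 4.4e-09. In each of these 12 genes both mTEC-I libraries lay beyond all 6 others. The gut and liver list, which holds Cdx1 and Foxa1 (-1.03, adjusted p = 1.0e-08), had 0 of 12 measured genes higher, 9 lower and 3 not called (0 and 10 adjusted over the list alone), with camera adjusted p = 1.8e-06, and adjusted p = 0.0578 with an estimated correlation. This list is set against a mean that holds mTEC-IV, where 10 of 12 of its genes were higher. How much of the fall comes from that rise was not tested.

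Genes of differentiated epithelium were lower in mTEC-I than in the mean of the other 3. The cornified epithelium list had 2 of 26 measured genes higher, 15 lower and 9 not called (2 and 15 adjusted over the list alone), with camera adjusted p = 5.5e-05, and adjusted p = 0.171 with an estimated correlation. Its falls included the corneodesmosome gene Cdsn (-1.83) and the epithelial transcription factor genes Ovol1 (-0.73), Ehf (-0.43) and Klf4 (-0.40), with adjusted p = 1.3e-06, 9.4e-06, 2.9e-05 and 9.3e-06. Ehf and Klf4 stood lower still in mTEC-II. The cornified list is set against a mean that holds mTEC-III, where 19 of 26 of its genes were higher. As a list, its fall cannot be told apart from that rise. The tuft cell list had 1 of 35 measured genes higher, 25 lower and 9 not called (2 and 27 adjusted over the list alone), with camera adjusted p = 6.1e-12, and adjusted p = 0.0578 with an estimated correlation. The bitter taste receptor list had 0 of 20 measured genes higher, 16 lower and 4 not called (1 and 16 adjusted over the list alone), with camera adjusted p = 2.3e-07, and adjusted p = 0.0578 with an estimated correlation. Both lists are set against a mean that holds mTEC-IV, where 33 of 35 tuft and 19 of 20 taste receptor genes were higher. As lists, their falls cannot be told apart from that rise. Pou2f3, the tuft cell transcription factor, stood at 329 ± 20.1 (-1.13 ± 0.074 SE, adjusted p = 2.6e-08), Rgs13 fell to 38.2 ± 8.3 (-2.01) and Gfi1b to 31.2 ± 1.5 (-2.15). The Aire-stage list had 1 of 16 measured genes higher, 6 lower and 9 not called (1 and 6 adjusted over the list alone), with camera adjusted p = 0.0396, and adjusted p = 0.447 with an estimated correlation. Cd80, a costimulatory molecule, fell by 0.34 (adjusted p = 9.2e-04), and H2-Eb2 of the MHC class II list was lower at 46.1 ± 7.0 (-1.80, adjusted p = 1.1e-07) while Cd74, the invariant chain, was higher (0.69, adjusted p = 1.5e-04). That list had 4 of 11 measured genes higher, 1 lower and 6 not called (5 and 1 adjusted over the list alone), with camera adjusted p = 0.144. The tight junction genes Cldn3 (-0.94), Cldn4 (-0.77) and Cldn7 (-1.13) were lower and the keratin gene Krt7 higher (1.06), with adjusted p = 2.9e-06, 1.6e-06, 6.9e-06 and 2.6e-07. Their pan-epithelial list had 6 of 20 measured genes higher, 11 lower and 3 not called (6 and 11 adjusted over the list alone), with camera adjusted p = 0.396.

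At the level of genes, 2702 were higher and 2783 lower in mTEC-I (49.3% higher), a share from 41.4% with RLE size factors to 54.4% with peaks within 20 kb of the start site. Counts in mTEC-I stayed within 1.5 times when any library was left out. Self-tests at these depths gave false calls in mTEC-I, 30 peaks and 54 genes, and few or none in the other populations. In mTEC-I the share of false calls was above what the threshold allows, in a simulation that changed far fewer peaks than differed in the data. The fit took 1 spread per peak or gene for all populations. The SD of the log2 difference between replicates over peaks was 0.835 in mTEC-I and 0.264 to 0.385 in the other populations. Adjusted p-values may therefore be too small in mTEC-I and too large in the others.

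In mTEC-II, genes of MHC class II presentation carried more H3K4me2. Ciita, the transactivator of MHC class II genes, stood at 523 ± 5.5 (SD, n = 2) against 155 to 342 (1.06 ± 0.099 SE, adjusted p = 5.0e-06). H2-Eb2 stood at 332 ± 24 against 46.1 to 122 (1.98 ± 0.14 SE, adjusted p = 1.1e-06), and the peptide-loading genes H2-DMb2 (0.53) and H2-Ob (1.21) rose as well (adjusted p = 2.8e-04 and 2.8e-04). The list had 9 of 11 measured genes higher, 0 lower and 2 not called (9 and 0 adjusted over the list alone), with camera adjusted p = 4.9e-09, and adjusted p = 0.153 with an estimated correlation. A peak in intron 1 of H2-Eb2 (chromosome 17, 34461773 to 34468043, mm9) and one in intron 4 of Zfp362 (chromosome 4, 128460925 to 128468765; 369 ± 18, 1.87 ± 0.12 SE, adjusted p = 4.3e-05) were the 2 higher peaks of smallest p.

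Genes of the Aire stage rose with them in mTEC-II. The costimulatory receptor gene Cd40 (0.75), Pdcd1lg2, which encodes PD-L2 (0.74), and the signalling adaptor gene Traf1 (0.80) were higher (adjusted p = 2.8e-04, 1.1e-04 and 3.5e-04). The list had 7 of 16 measured genes higher, 1 lower and 8 not called (7 and 1 adjusted over the list alone), with camera adjusted p = 1.2e-05, and adjusted p = 0.171 with an estimated correlation. Aire itself, the regulator of tissue antigen expression, was assigned no peak, but a peak in exon 3 of Aire, nearest to the start of Dnmt3l, was picked out after its values were seen (chromosome 10, 77503091 to 77507627). It stood at 214 ± 2.8 in mTEC-II against 69.1 to 104.2 (1.26 ± 0.14 SE, adjusted p = 2.2e-04). Foxn1, the master regulator of thymic epithelium, reached 608 ± 2.0 against 180 to 458 (0.87 ± 0.075 SE, adjusted p = 3.1e-06). The cortical epithelial list that holds it had 5 of 14 measured genes higher, 0 lower and 9 not called (6 and 2 adjusted over the list alone), with camera adjusted p = 6.7e-04, and adjusted p = 0.370 with an estimated correlation. The number higher moved with the scaling, to 8 with RLE size factors or equal totals and 7 with loess. Fezf2, another regulator of tissue antigens, stood at 1863 ± 22 in mTEC-II (0.32, adjusted p = 1.9e-04), 1972 ± 38 in mTEC-III (0.43, adjusted p = 6.0e-06) and 1184 ± 50.03 in mTEC-I (-0.55, adjusted p = 2.7e-07). The directions in mTEC-I and mTEC-II turned, without passing the threshold, when only peaks within 20 kb of the start site were summed (0.024 and -0.026).

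The largest rises in mTEC-II by the rule were at A930019D19Rik (1.45), Mir7657 (1.41), Hoxc11 (1.27), Cox4i1 (1.27), 5330413P13Rik (1.19), the neuropeptide receptor gene Qrfpr (1.16), Gad1os (1.09) and the cytokine gene Il13 (434 ± 3.1, 1.08), with adjusted p from 1.1e-06 to 0.0058. Gad1os no longer passed without mTEC-II replicate 1 (1.07, adjusted p = 0.0756) or 2 (1.11, adjusted p = 0.0621), with 1 mTEC-II library left in each case. The largest falls were at Slitrk6 (78.8 ± 3.7, -1.78), Rab27b, a GTPase of vesicle secretion (-1.18), Gm6639 (-1.08) and Rtp4 (-1.06), with adjusted p from 2.6e-07 to 3.0e-06. In these 12 genes both mTEC-II libraries lay beyond the 6 others. Hoxc11 stood at 343 in mTEC-II, 285 in mTEC-III and 236 in mTEC-IV, so its rise is against a mean that holds a low mTEC-I (41.5). The interferon list had 2 of 19 measured genes higher, 9 lower and 8 not called (2 and 12 adjusted over the list alone), with camera adjusted p = 0.0039, and adjusted p = 0.173 with an estimated correlation. Its falls included Irf9 (-0.999, adjusted p = 2.6e-06) and Rsad2 (-0.88, adjusted p = 2.3e-04). This list is set against a mean that holds mTEC-I, where 16 of 19 of its genes were higher. The cornified list had 2 of 26 measured genes higher, 13 lower and 11 not called (2 and 14 adjusted over the list alone), with camera adjusted p = 0.0012, and adjusted p = 0.215 with an estimated correlation. Ehf stood at 707 ± 14 (-0.69) and Klf4 at 911 ± 6.0 (-0.48). The cornified list is set against a mean that holds mTEC-III, where 19 of 26 of its genes were higher. As lists, the interferon and cornified falls cannot be told apart from those rises. The tuft list had 3 of 35 measured genes higher, 22 lower and 10 not called (4 and 25 adjusted over the list alone), with camera adjusted p = 3.8e-08, and adjusted p = 0.0635 with an estimated correlation. Among its falls were Runx1 (-0.67) and Pou2f3 (-0.76). Bitter taste receptor genes showed 0 of 20 measured genes higher, 10 lower and 10 not called (0 and 13 adjusted over the list alone), with camera adjusted p = 1.6e-04, and adjusted p = 0.0974 with an estimated correlation. The tuft and taste receptor lists are again set against a mean that holds mTEC-IV, where 33 of 35 and 19 of 20 genes were higher. As lists, their falls cannot be told apart from that rise.

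Genes of other tissues were among those higher in mTEC-II. The neuroendocrine list had 7 of 15 measured genes higher, 1 lower and 7 not called (10 and 1 adjusted over the list alone), with camera adjusted p = 1.1e-04, and adjusted p = 0.361 with an estimated correlation. Insm1, a neuroendocrine transcription factor gene, rose by 0.49, adjusted p = 6.2e-04. The muscle list had 3 of 8 measured genes higher, 1 lower and 4 not called (4 and 1 adjusted over the list alone), with camera adjusted p = 0.0245, and adjusted p = 0.447 with an estimated correlation. Gut and liver genes had 3 of 12 measured genes higher, 2 lower and 7 not called (3 and 2 adjusted over the list alone), with camera adjusted p = 0.0438, and adjusted p = 0.252 with an estimated correlation. Runx3 (0.90, adjusted p = 3.1e-05) of the thymocyte list was higher, but not when only peaks within 20 kb of its start were used (0.60, adjusted p = 0.213). That list had 2 of 12 measured genes higher, 0 lower and 10 not called (2 and 0 adjusted over the list alone), with camera adjusted p = 0.0061, and adjusted p = 0.343 with an estimated correlation. Pax5, a B cell transcription factor gene, stood at 178 ± 16 in mTEC-II (1.15, adjusted p = 3.5e-05). The antigen-presenting haematopoietic list had 2 of 12 measured genes higher, 1 lower and 9 not called (3 and 2 adjusted over the list alone), with camera adjusted p = 0.593. The basal list had 2 of 18 measured genes higher, 4 lower and 12 not called (3 and 4 adjusted over the list alone), with camera adjusted p = 0.770. Its balance turned with the scaling, to 4 higher and 3 lower with RLE size factors or loess and 5 and 3 with equal totals. Pan-epithelial genes had 1 of 20 measured genes higher, 4 lower and 15 not called (1 and 5 adjusted over the list alone), with camera adjusted p = 0.841. These were 2 higher and 2 lower with RLE size factors, 2 and 1 with equal totals and 1 and 3 with loess.

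At the level of genes, 1347 were higher and 1759 lower in mTEC-II (43.4% higher). This balance turned with the scaling: the share of higher genes was 64.6% with RLE size factors, 65.7% with equal totals in peaks, 61.3% with loess, 63.1% with DESeq2, 61.9% with edgeR and 59.8% with voom. Of the peaks called in mTEC-II 58.6% were higher, and 72.6% with equal totals. Single libraries also moved the counts. Without mTEC-II replicate 1, 311 higher and 242 lower peaks and 372 higher and 411 lower genes were called, and without replicate 2, 323 and 253 peaks and 351 and 445 genes. Without mTEC-I replicate 1 the counts rose to 5870 and 5113 peaks and 2256 and 3393 genes, and without mTEC-I replicate 2 to 5050 and 4653 peaks and 3065 lower genes. Lower peaks came to 1304 without mTEC-IV replicate 1 and 1301 without replicate 2, and lower genes to 1149 without replicate 2.

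In mTEC-III, genes of cornified epithelium carried more H3K4me2. Spink5, a protease inhibitor of the epidermis, stood at 562 ± 16 (SD, n = 2) against 54.9 to 118 (2.62 ± 0.11 SE, adjusted p = 2.2e-09). Tgm1, which cross-links the cornified envelope, stood at 265 ± 7.3 against 45.6 to 111 (1.86 ± 0.14 SE, adjusted p = 2.6e-07), and the desmocollin gene Dsc1 at 161 ± 5.7 against 13.5 to 38.2 (2.81 ± 0.26 SE, adjusted p = 1.7e-06). The list had 19 of 26 measured genes higher, 1 lower and 6 not called (19 and 1 adjusted over the list alone), with camera adjusted p = 6.0e-12, and adjusted p = 0.0578 with an estimated correlation. The 2 higher peaks of smallest p lay in intron 2 of Spink5 (chromosome 18, 44121332 to 44129288, mm9; 2.68 ± 0.12 SE, adjusted p = 1.2e-06) and intron 2 of Skint3 (chromosome 4, 111903780 to 111914386; 1.68 ± 0.084 SE, adjusted p = 2.2e-06).

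The largest rises in mTEC-III by the rule were at Ide, the insulin-degrading enzyme (512 ± 32, 1.79), the butyrophilin-like genes Skint3 (1.65), Skint8 (1.60) and Skint4 (1.39), the tight junction gene Cldn1 (583 ± 34, 1.41), Dapl1 (1.40), the lipase gene Liph (1.28) and the chloride channel gene Clic3 (1.27), with adjusted p from 3.6e-08 to 1.1e-04. The largest falls were at Gfra2, a neurturin receptor (153 ± 31, -1.53), Mir181a-2 (-1.45), A330049N07Rik (-1.39) and the signalling adaptor gene Sh2b2 (-1.35), with adjusted p from 1.3e-07 to 4.2e-07. In these 12 genes both mTEC-III libraries lay beyond the 6 others.

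More basal genes were lower than higher in mTEC-III, and Krt5 was among the higher (0.81, adjusted p = 2.3e-04). The chemokine-scavenging receptor gene Ackr4 (52.6 ± 7.7, -1.68), Igfbp5 (-0.93), Bcam (-1.23) and Lifr (-0.54) fell (adjusted p = 1.9e-07, 3.0e-07, 2.4e-05 and 1.1e-05). Their list had 2 of 18 measured genes higher, 9 lower and 7 not called (2 and 11 adjusted over the list alone), with camera adjusted p = 6.7e-04, and adjusted p = 0.226 with an estimated correlation. The basal list is set against a mean that holds mTEC-I, where 10 of 18 of its genes were higher. How much of the fall comes from that rise was not tested. The fibroblast list had 1 of 13 measured genes higher, 7 lower and 5 not called (1 and 9 adjusted over the list alone), with camera adjusted p = 0.0012, and adjusted p = 0.182 with an estimated correlation. Its falls included Prrx1 (-0.85), Col6a1 (-0.94) and Dcn (-1.82), with adjusted p = 3.8e-05, 1.4e-04 and 1.8e-04. The endothelial list, with the receptor genes Tek (-0.94, adjusted p = 1.3e-04) and Kdr (-0.60, adjusted p = 2.7e-04), had 0 of 14 measured genes higher, 7 lower and 7 not called (0 and 7 adjusted over the list alone), with camera adjusted p = 0.0187, and adjusted p = 0.447 with an estimated correlation. The cortical epithelial list had 1 of 14 measured genes higher, 5 lower and 8 not called (1 and 6 adjusted over the list alone), with camera adjusted p = 0.0293, and adjusted p = 0.540 with an estimated correlation. Of its genes Cxcl12 (-0.66) and Il7 (-0.36) fell. The neuroendocrine list had 0 of 15 measured genes higher, 5 lower and 10 not called (0 and 6 adjusted over the list alone), with camera adjusted p = 0.0233, and adjusted p = 0.556 with an estimated correlation. The tuft list had 0 of 35 measured genes higher, 25 lower and 10 not called (0 and 27 adjusted over the list alone), with camera adjusted p = 8.4e-12, and adjusted p = 0.0578 with an estimated correlation. The leukotriene gene Alox5ap (-1.21) and Dclk1 (-0.87) fell. The bitter taste receptor list had 0 of 20 measured genes higher, 13 lower and 7 not called (0 and 14 adjusted over the list alone), with camera adjusted p = 5.4e-06, and adjusted p = 0.0635 with an estimated correlation. Here too the tuft and taste receptor lists are set against a mean that holds the high mTEC-IV (33 of 35 and 19 of 20 genes higher). As lists, their falls cannot be told apart from that rise. The MHC class II list had 0 of 11 measured genes higher, 1 lower and 10 not called (0 and 1 adjusted over the list alone), with camera adjusted p = 0.921. Aire-stage genes had 3 of 16 measured genes higher, 3 lower and 10 not called (4 and 3 adjusted over the list alone), with camera adjusted p = 0.921. Pan-epithelial genes had 6 of 20 measured genes higher, 8 lower and 6 not called (6 and 8 adjusted over the list alone), with camera adjusted p = 0.803. Itgax, an integrin gene of dendritic cells, was higher in mTEC-III (2.29, adjusted p = 8.2e-05). Its haematopoietic list had 2 of 12 measured genes higher, 2 lower and 8 not called (2 and 3 adjusted over the list alone), with camera adjusted p = 0.736.

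At the level of genes, 1908 were higher and 2622 lower in mTEC-III (42.1% higher), a share that was 50% with voom. Of called peaks 44.4% were higher, and 51.9% with loess, 50.6% with edgeR and 51.9% with voom. Without mTEC-III replicate 1 the counts were 1158 higher and 1362 lower peaks and 1120 higher and 1244 lower genes, and without replicate 2, 1239 and 2625 peaks and 951 higher genes (31.3% of those called). Without mTEC-I replicate 1 there were 5941 higher and 6571 lower peaks and 3013 higher genes, and without mTEC-I replicate 2, 5217 higher and 6710 lower peaks.

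In mTEC-IV, genes of tuft cells, the chemosensory cells of gut and airway epithelium, carried far more H3K4me2. Trpm5, the cation channel of taste transduction, stood at 632 ± 42 (SD, n = 2) against 19.6 to 35.9 (4.55 ± 0.18 SE, adjusted p = 5.9e-11). Pou2f3 stood at 1528 ± 19 against 329 to 611 (1.83 ± 0.074 SE, adjusted p = 7.8e-11), Rgs13 at 1050 ± 34 against 38.2 to 61.8 (4.33 ± 0.14 SE, adjusted p = 1.1e-11) and Lrmp at 1321 ± 16 (3.59, adjusted p = 1.1e-11). The list had 33 of 35 measured genes higher, 0 lower and 2 not called (34 and 0 adjusted over the list alone), with camera adjusted p = 3.0e-29, and adjusted p = 0.0507 with an estimated correlation. The median change was 1.98. The bitter taste receptor list had 19 of 20 measured genes higher, 0 lower and 1 not called (19 and 1 adjusted over the list alone), with camera adjusted p = 2.2e-14, and adjusted p = 0.0507 with an estimated correlation. Tas2r108 rose to 552 ± 3.2 from 18.7 to 31.3 (4.47 ± 0.21 SE, adjusted p = 3.2e-10) and Tas2r115 by 4.36, adjusted p = 2.7e-10. Inside Chat, which makes the transmitter acetylcholine, peaks given to neighbouring genes were picked out after their values were seen. One in intron 3 (chromosome 14, 33269092 to 33274346, mm9) stood at 298 ± 16 against 6.81 to 27.02 (4.56 ± 0.26 SE, adjusted p = 2.9e-07), and one in intron 12 (chromosome 14, 33231022 to 33234910) at 196 ± 14 (4.16 ± 0.33 SE, adjusted p = 3.4e-06).

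The largest rises in mTEC-IV by the rule were at Lrmp, the synaptic adhesion gene Slitrk6 (1019 ± 11, 3.12), Pik3cg and Pik3r5, the catalytic and regulatory subunits of a phosphoinositide 3-kinase (3.00 and 2.72), the zinc finger gene St18 (2.98), Mctp1 (2.53), the cytokine gene Il10 (686 ± 24 against 88.5 to 193, 2.45) and D930032P07Rik (2.36), with adjusted p from 1.9e-13 to 3.4e-09. The 2 higher peaks of smallest p lay in intron 1 of Mctp1 (chromosome 13, 76676582 to 76696438; 1770 ± 23, 3.76 ± 0.089 SE, adjusted p = 1.0e-09) and intron 2 of Pik3cg (chromosome 12, 32879018 to 32895634; 1198 ± 42, 3.38 ± 0.12 SE, adjusted p = 3.6e-08). The rise of Mctp1 did not pass with peaks within 20 kb of its start alone (0.27, adjusted p = 0.0750). Gut and liver genes rose as well. Their list had 10 of 12 measured genes higher, 0 lower and 2 not called (10 and 0 adjusted over the list alone), with camera adjusted p = 5.4e-06, and adjusted p = 0.0609 with an estimated correlation. The fatty acid binding protein gene Fabp1 stood at 258 ± 35 against 10.7 to 17.4 (4.12 ± 0.27 SE, adjusted p = 1.0e-08). The secretory cell factor gene Spdef rose by 2.69, adjusted p = 7.2e-08, and Cdx1 by 1.27, adjusted p = 2.7e-06. The pan-epithelial list had 10 of 20 measured genes higher, 4 lower and 6 not called (10 and 4 adjusted over the list alone), with camera adjusted p = 0.151. Krt8 and Krt18, keratins of simple epithelium, rose by 1.08, adjusted p = 3.6e-09, and 0.85, adjusted p = 5.9e-08.

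Some genes of blood and endothelial cells were higher in mTEC-IV, although none of their lists was called. Beside Ptprc, the B cell genes Cd79a (67.4 ± 14, 2.65, adjusted p = 3.7e-05), Cd79b (124 ± 1.2, 1.76, adjusted p = 1.9e-05) and Pax5 (176 ± 7.9, 1.13, adjusted p = 7.5e-06) were higher, as were Mpeg1 of macrophages (0.91, adjusted p = 3.7e-04) and Themis of thymocytes (1.79, adjusted p = 1.7e-04). The haematopoietic list had 6 of 12 measured genes higher, 2 lower and 4 not called (6 and 4 adjusted over the list alone), with camera adjusted p = 0.371. Thymocyte genes had 2 of 12 measured genes higher, 3 lower and 7 not called (2 and 3 adjusted over the list alone), with camera adjusted p = 0.921. The endothelial genes Tek and Cdh5 rose by 2.21, adjusted p = 7.7e-09, and 3.10, adjusted p = 1.9e-06. Endothelial genes had 6 of 14 measured genes higher, 1 lower and 7 not called (8 and 2 adjusted over the list alone), with camera adjusted p = 0.0825.

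The MHC class II and interferon lists were lower in mTEC-IV, while basal genes went both ways. With an estimated correlation neither list was called (adjusted p = 0.171 and 0.300). Krt5 fell to 29.6 ± 4.7 (-2.66 ± 0.13 SE, adjusted p = 4.3e-10), and Krt17 (-3.25), Serpina3i (-3.12), Serpina3h (-2.68) and Mill1 (-2.38) were the largest falls by the rule, with adjusted p from 4.9e-11 to 3.2e-10. In the 8 highest and these 4 lowest genes both mTEC-IV libraries lay beyond the 6 others. Krt14 fell by 1.95 (adjusted p = 2.1e-08) while Ackr4 of the same list rose to 494 ± 7.5 (2.61, adjusted p = 3.1e-10). Basal genes had 4 of 18 measured genes higher, 6 lower and 8 not called (4 and 6 adjusted over the list alone), with camera adjusted p = 0.281. Ciita (155 ± 10.3, -1.27) and Cd74 (-1.17) fell (adjusted p = 6.5e-08 and 4.7e-07). MHC class II genes had 0 of 11 measured genes higher, 9 lower and 2 not called (0 and 9 adjusted over the list alone), with camera adjusted p = 2.3e-07, and adjusted p = 0.171 with an estimated correlation. Foxn1 fell to 180 ± 7.3 (-1.46, adjusted p = 6.6e-10) and Ccl25 by 0.60 (adjusted p = 0.0010). Cortical epithelial genes had 1 of 14 measured genes higher, 7 lower and 6 not called (1 and 9 adjusted over the list alone), with camera adjusted p = 0.0051, and adjusted p = 0.447 with an estimated correlation. Ifit3 (-2.31) and Mx1 (-2.09) fell while Rsad2 rose (0.76), with adjusted p = 1.6e-08, 3.1e-08 and 2.3e-04. Their list had 3 of 19 measured genes higher, 8 lower and 8 not called (4 and 8 adjusted over the list alone), with camera adjusted p = 0.0378, and adjusted p = 0.300 with an estimated correlation. The interferon list is set against a mean that holds mTEC-I, where 16 of 19 of its genes were higher. As a list, its fall cannot be told apart from that rise. The cornified list had 6 of 26 measured genes higher, 7 lower and 13 not called (7 and 7 adjusted over the list alone), with camera adjusted p = 0.251. Its genes Ehf (1.12) and Klf4 (0.89) were higher. Aire-stage genes had 3 of 16 measured genes higher, 7 lower and 6 not called (3 and 7 adjusted over the list alone), with camera adjusted p = 0.151.

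At the level of genes, 3214 were higher and 1988 lower in mTEC-IV (61.8% higher), a share that was 44.2% with equal totals in peaks and 42.4% with voom. Of called peaks 62.1% were higher, and 50.5% with equal totals, 45.0% with loess and 49.2% with voom. Without mTEC-IV replicate 1 there were 3465 higher and 2577 lower peaks and 2081 higher and 1101 lower genes, and without replicate 2, 3144 and 2369 peaks and 1899 and 1062 genes.

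**Figure D3:**
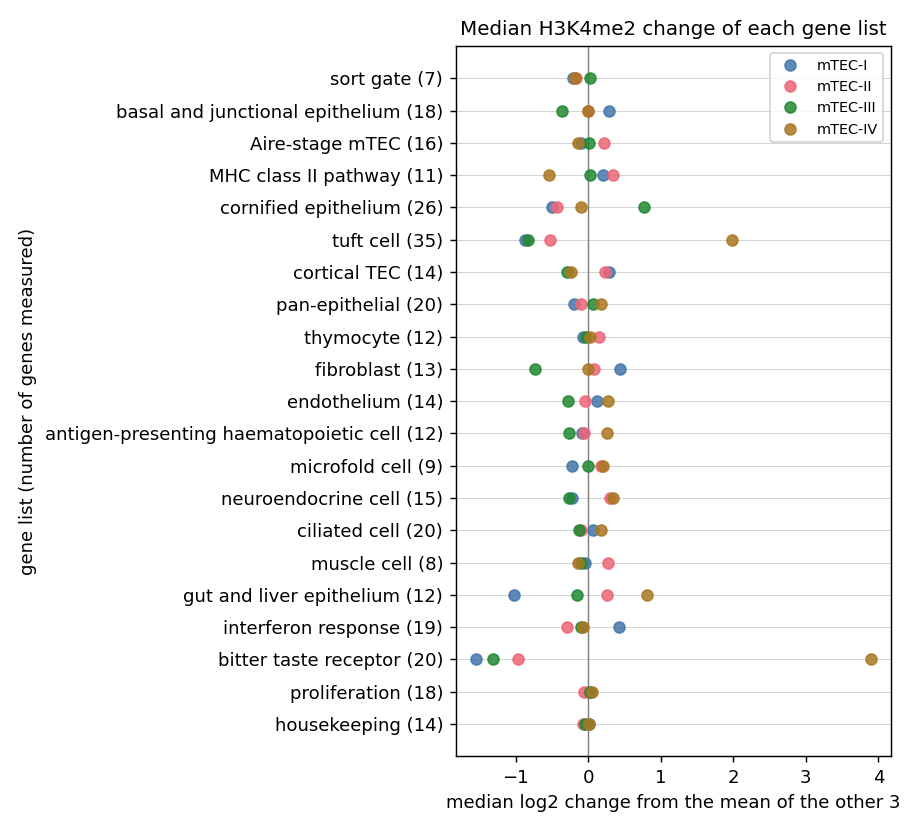
Median log2 change of H3K4me2 in 21 gene lists, with 1 point per mTEC population against the mean of the other 3 and the number of genes measured in brackets. Bitter taste receptor genes in mTEC-IV had the largest median of the 84, 3.89, and tuft cell genes in mTEC-IV the next largest, 1.98.

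The remaining lists were not called. Proliferation genes had 1 higher and 0 lower of 18 in mTEC-I, 1 and 0 in mTEC-II, 0 and 2 in mTEC-III, and 2 and 2 in mTEC-IV (camera adjusted p between 0.770 and 0.921, not called). Adjusted over the list alone, these were 0 and 0, 1 and 0, 0 and 0, and 2 and 2. Housekeeping genes had 4 and 0, 0 and 2, 0 and 1, and 3 and 1 of 14 in the same order (camera adjusted p = 0.561, 0.424, 0.921 and 0.921), and adjusted over the list alone 4 and 0, 0 and 2, 0 and 1, and 4 and 2. These counts moved with the scaling, to 1 and 2 in mTEC-IV with equal totals and 2 and 0 in mTEC-I with RLE size factors. Ciliated cell genes had 3 and 4, 1 and 0, 1 and 6, and 6 and 3 of 20 (camera adjusted p = 0.889, 0.921, 0.216 and 0.480), and over the list alone 5 and 4, 0 and 0, 1 and 6, and 8 and 3. Microfold cell genes had 0 and 3, 3 and 2, 2 and 2, and 2 and 3 of 9 (camera adjusted p = 0.113, 0.216, 0.921 and 0.893), and over the list alone 0 and 3, 4 and 2, 3 and 2, and 3 and 3. In mTEC-I the neuroendocrine list had 2 of 15 measured genes higher, 6 lower and 7 not called (2 and 6 adjusted over the list alone), with camera adjusted p = 0.110. The homeobox gene Pax6 fell by 0.997 (adjusted p = 9.7e-08) and Isl1 rose (0.85, adjusted p = 1.3e-07). Further lists without a call were muscle, thymocyte, endothelial and haematopoietic genes in mTEC-I (camera adjusted p = 0.833, 0.567, 0.921 and 0.207), fibroblast and endothelial genes in mTEC-II (0.333 and 0.889), gut and liver, interferon, muscle and thymocyte genes in mTEC-III (0.333, 0.405, 0.478 and 0.596), and muscle, neuroendocrine and fibroblast genes in mTEC-IV (0.736, 0.333 and 0.841). Median, mean and camera direction differed in sign only in lists without a call (camera adjusted p of 0.593 or more), among them sort gate genes (median -0.18, mean 0.44) and muscle genes (-0.15 and 0.42) in mTEC-IV.

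Between pairs of populations, the most peaks differed between mTEC-I and mTEC-IV, 11978, of which 7513 were higher in mTEC-IV, and the fewest between mTEC-II and mTEC-III, 5179, of which 2266 were higher in mTEC-III. The order changed with the test: DESeq2, edgeR and voom gave the most for mTEC-III and mTEC-IV (12104, 14475 and 15463) and the fewest for mTEC-I and mTEC-II (7042, 8918 and 8329). So did leaving out mTEC-I replicate 2 (14615 and 8793), and without mTEC-IV replicate 1 or 2 the most were for mTEC-I and mTEC-III (7921 and 7929). The other pairs in the limma fit were 10404 for mTEC-III and mTEC-IV, 9076 for mTEC-I and mTEC-III, 8869 for mTEC-II and mTEC-IV and 7451 for mTEC-I and mTEC-II. Every pair moved by over 1.5 times with a library. mTEC-I and mTEC-II differed at 12690 peaks without mTEC-I replicate 1 and at 2477 and 2434 without mTEC-II replicates 1 and 2, and mTEC-I and mTEC-III at 4957 and 5756 without mTEC-III replicates 1 and 2. mTEC-I and mTEC-IV differed at 7637 and 7519 without mTEC-IV replicates 1 and 2. mTEC-II and mTEC-III differed at 10967 and 10960 without mTEC-I replicates 1 and 2, at 916 and 909 without those of mTEC-II and at 1284 and 2594 without those of mTEC-III. mTEC-II and mTEC-IV differed at 4605 and 4576 without mTEC-II replicates 1 and 2 and at 4651 and 4362 without those of mTEC-IV. mTEC-III and mTEC-IV differed at 6421 without mTEC-III replicate 1 and at 5818 and 5162 without mTEC-IV replicates 1 and 2.

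Peaks away from promoters differed more often among the populations than promoter peaks. Of 18139 distal peaks 12842 differed (70.8%), and of 11330 peaks within 1 kb of a start site 4299 (37.9%), with no test over peaks, which are not replicates. Of all tested peaks 61.6% were distal. Among peaks higher in a population the distal share was 53.4% in mTEC-I, 87.1% in mTEC-II, 72.6% in mTEC-III and 83.5% in mTEC-IV, and among lower peaks 86.1%, 66.5%, 67.5% and 77.8%. These shares were not recomputed under other settings, and lower peaks in mTEC-I numbered 6814 here, 5171 with loess and 5049 with voom. Of 6747 peaks listed for all 4 populations, 1817 were higher and 257 lower in mTEC-I. With the filter at 50, which removes weak peaks, 3974 higher and 4910 lower peaks were called in mTEC-I, against 4338 and 6814 in the main fit. Lower calls in mTEC-I thus depended more on weak peaks than higher calls did. Whether the distal shares in mTEC-I follow signal level was not tested.

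The authors' deposited lists held 7036 peaks for mTEC-I, 23949 for mTEC-II, 19321 for mTEC-III and 22757 for mTEC-IV. Merged over the lists there were 29472 regions, of which 6747 were listed for all 4 populations and 9082 for all but mTEC-I. Regions listed for a single population numbered 13 for mTEC-I, 4433 for mTEC-II, 1405 for mTEC-III and 3970 for mTEC-IV. With an equal number of top peaks from each list these were 887, 418, 474 and 760, with the most for mTEC-I, and 837 regions were listed for all but mTEC-I. The lists began at different levels: the lowest signal listed was 142.7 tags per 10000000 for mTEC-I, 33.4 for mTEC-II, 40.8 for mTEC-III and 41.8 for mTEC-IV. At or above 142.7 the lists held 7036, 7820, 8473 and 8493 peaks. The authors' median fold over control was 19.8 for mTEC-I, 16 for mTEC-II, 17.9 for mTEC-III and 16.4 for mTEC-IV.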

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

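The 2 mitochondrial peaks of the merged table entered no comparison and held tags in every library, above the 3 tags that a count of 0 allows. They held 535 and 4293.5 tags in mTEC-I replicates 1 and 2, 6017.5 and 815.5 in mTEC-II, 257 and 233.5 in mTEC-III, and 339.5 and 380 in mTEC-IV.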

How the results depend on the processing

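Tests with edgeR and voom, the pseudocount of 5 and the filter at 50 were chosen only after the result was seen. For the changes below the cause was not tested. The 4 gene lists tied to a population kept their direction and their call under equal totals, loess, the 20 kb limit, a block and without each library. They are basal genes in mTEC-I, Aire-stage genes in mTEC-II, cornified genes in mTEC-III and tuft genes in mTEC-IV. With an estimated correlation these 4 were no longer called, at 0.171, 0.171, 0.0579 and 0.0507. Depth limits mTEC-I most: replicate 2 held 1702103.5 tags, and a count of 0 there allows up to 17.6 tags per 10000000.

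Leaving out a library leaves fewer samples and 1 lone sample in its population, assumed to vary like the others. The ranges were 12678 to 22352 for peaks differing among the 4 populations. For higher and lower peaks they were 3033 to 5848 and 5296 to 8487 in mTEC-I, 311 to 5870 and 242 to 5113 in mTEC-II, 1158 to 5941 and 1362 to 6710 in mTEC-III, and 3144 to 8997 and 2369 to 5826 in mTEC-IV. For higher and lower genes they were 1992 to 3587 and 2319 to 3601 in mTEC-I, 351 to 2256 and 411 to 3393 in mTEC-II, 951 to 3013 and 1244 to 3519 in mTEC-III, and 1899 to 4134 and 1062 to 2834 in mTEC-IV. For pairs they were 2434 to 12690 (mTEC-I and mTEC-II), 4957 to 13537 (mTEC-I and mTEC-III), 7519 to 15508 (mTEC-I and mTEC-IV), 909 to 10967 (mTEC-II and mTEC-III), 4362 to 12810 (mTEC-II and mTEC-IV) and 5162 to 14615 (mTEC-III and mTEC-IV). Of named genes not past the threshold, L1cam in mTEC-I ranged from -0.60 to 0.011, Epcam in mTEC-III from -0.069 to 0.18 and H2-Aa in mTEC-III from -0.10 to 0.14. Over all named genes and libraries left out, 1367 values kept their side of the threshold and their sign, 9 passed newly, 13 no longer passed and 3 turned.

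Of the scalings, RLE size factors gave 1046 lower genes in mTEC-II. Equal totals in peaks gave 1016 lower genes in mTEC-II and 3324 in mTEC-IV. Loess gave 1095 lower genes in mTEC-II and 4530 higher peaks in mTEC-IV. No scaling moved the median change of all peaks or genes by over 0.1. DESeq2 gave 4760 higher peaks and 2220 higher genes in mTEC-II, and 8164 peaks between mTEC-II and mTEC-III. edgeR gave 5864 higher and 3695 lower peaks in mTEC-II, 5635 higher in mTEC-III, 6623 lower in mTEC-IV, and 10978 between mTEC-II and mTEC-III. Its higher and lower genes were 2254 and 2929 in mTEC-I, 2870 and 1764 in mTEC-II, 2439 and 3522 in mTEC-III, and 3715 and 2863 in mTEC-IV. voom gave 7221 higher and 3409 lower peaks in mTEC-II, 5776 higher in mTEC-III, 7760 lower in mTEC-IV, 12233 between mTEC-II and mTEC-III and 14535 between mTEC-II and mTEC-IV. It also gave 3193 higher genes in both mTEC-II and mTEC-III and 4316 lower genes in mTEC-IV. The filter at 50 gave 1993 higher peaks in mTEC-II. Other counts of peaks and genes, including those without a filter and with a pseudocount of 5, stayed within 1.5 times. Itgb4 in mTEC-II, not past the threshold, turned to 0.027 with RLE, 0.032 with equal totals, 0.046 with loess, 0.015 with DESeq2, 0.020 with edgeR and 0.013 with voom. H2-Aa in mTEC-III turned to -0.0067 with loess and -0.0029 with edgeR. With peaks within 20 kb, Fezf2 turned to 0.024 in mTEC-I and -0.026 in mTEC-II. Over these settings 1877 values of named genes kept their side and sign, 13 passed newly, 7 no longer passed and 10 turned.

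The share of differing promoter peaks was 43.1% with a 3 kb window and 36.7% among the peaks of middle level. The share of differing distal peaks was 71.5% and 61.9%. Regions listed for mTEC-I alone numbered 611 with reciprocal overlap of 0.5 of each peak, 31 with the stronger 0.5 of each list and 887 with an equal number of top peaks. For mTEC-III alone these were 2805, 383 and 474, and for mTEC-IV alone 6048, 1262 and 760. For mTEC-II alone the last 2 were 1473 and 418, for all 4 populations 3196 and 4241, and for all but mTEC-I 5303 and 837.

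Same-numbered libraries showed no shared deviation: their deviations from group means correlated between -0.0125 and 0.0159 over the 6 pairs of populations. Counted in whole tags, replicates differed little beyond counting error (chi-square per degree of freedom 1 to 1.065). The correlations therefore cannot show whether samples were paired. The replicate number as a block changed no count of calls by over 1.5 times, and of named genes it changed the call of Epcam in mTEC-II alone (-0.18, adjusted p = 0.0450). With it, higher and lower peaks were 4281 and 6747 in mTEC-I, 2899 and 2042 in mTEC-II, 3216 and 4058 in mTEC-III, and 6872 and 4162 in mTEC-IV. Higher and lower genes were 2662 and 2752, 1334 and 1715, 1858 and 2592, and 3187 and 1953.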

Other observations

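The families below, the peak list floor and the fibroblast, thymocyte, B cell and myeloid tests were chosen only after the results were seen. Homeobox genes of the Hox clusters carried less H3K4me2 in mTEC-I. Hoxc genes had 0 of 7 higher and 7 lower, median -1.60, camera adjusted p = 2.5e-09, and adjusted p = 0.124 with an estimated correlation, and Hoxb genes 0 of 9 higher and 7 lower, median -1.81, camera adjusted p = 5.8e-06, and adjusted p = 0.124 with an estimated correlation. Hoxa genes had 1 of 9 higher and 7 lower, median -1.14, camera adjusted p = 0.0015, and adjusted p = 0.124 with an estimated correlation, and Hoxd genes 0 of 7 higher and 5 lower, median -0.79, camera adjusted p = 0.0015, and adjusted p = 0.124 with an estimated correlation. The exception among the Hox genes was Hoxa2, which was higher in mTEC-I (1.38, adjusted p = 3.3e-08), at 1031 against 268 to 548. Hoxa6, Hoxa9, Hoxb5, Hoxb8, Hoxb13, Hoxc6 and Hoxd10, all called lower, had mTEC-I means of 4.88 to 14. These lie under the 17.6 tags per 10000000 that a count of 0 allows in mTEC-I replicate 2, so the size of their falls is uncertain. Values in the other populations are against a mean that holds this low mTEC-I. In mTEC-II, Hoxb had 5 of 9 higher and 0 lower, median 0.64, camera adjusted p = 3.0e-04, and adjusted p = 0.124 with an estimated correlation, Hoxc 5 of 7 higher and 0 lower, median 0.49, camera adjusted p = 4.4e-05, and adjusted p = 0.148 with an estimated correlation, Hoxa 1 of 9 higher and 1 lower, median 0.26, camera adjusted p = 0.0386, and adjusted p = 0.160 with an estimated correlation and Hoxd 0 of 7 higher and 0 lower, median 0.14, camera adjusted p = 0.339. In mTEC-III, Hoxc had 5 of 7 higher and 0 lower, median 0.44, camera adjusted p = 5.4e-04, and adjusted p = 0.156 with an estimated correlation, Hoxa 0 of 9 higher and 1 lower, median 0.10, camera adjusted p = 0.629, Hoxb 1 of 9 higher and 0 lower, median 0.18, camera adjusted p = 0.350 and Hoxd 3 of 7 higher and 0 lower, median 0.26, camera adjusted p = 0.127. In mTEC-IV, Hoxa had 5 of 9 higher and 1 lower, median 0.83, camera adjusted p = 0.0094, and adjusted p = 0.148 with an estimated correlation, Hoxb 6 of 9 higher and 0 lower, median 0.76, camera adjusted p = 0.0211, and adjusted p = 0.156 with an estimated correlation, Hoxc 6 of 7 higher and 0 lower, median 0.63, camera adjusted p = 0.0010, and adjusted p = 0.160 with an estimated correlation and Hoxd 2 of 7 higher and 0 lower, median 0.27, camera adjusted p = 0.281. Families tested numbered 8, with p-values adjusted over 32 tests, and no gene call in these families turned under another scaling. Hoxa genes in mTEC-II had 3 higher and 1 lower with RLE size factors, equal totals and loess alike.

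Skint genes, butyrophilin-like genes of epithelium, carried more H3K4me2 in mTEC-III, with 9 of 10 higher and 0 lower, median 0.89, camera adjusted p = 3.2e-09, and adjusted p = 0.124 with an estimated correlation. In mTEC-IV they had 1 of 10 higher and 6 lower, median -0.71, camera adjusted p = 4.5e-05, and adjusted p = 0.156 with an estimated correlation, in mTEC-II 4 of 10 higher and 2 lower, median 0.054, camera adjusted p = 0.339, and in mTEC-I 4 higher and 4 lower, with a median near 0 whose sign turned with the scaling (camera adjusted p = 0.428). Schlafen genes, several of them interferon-induced, had 5 of 5 higher and 0 lower, median 0.57, camera adjusted p = 5.4e-04, and adjusted p = 0.148 with an estimated correlation in mTEC-I, 0 of 5 higher and 1 lower, median -0.23, camera adjusted p = 0.0148, and adjusted p = 0.197 with an estimated correlation in mTEC-II, 0 of 5 higher and 3 lower, median -0.52, camera adjusted p = 0.0113, and adjusted p = 0.190 with an estimated correlation in mTEC-III and 2 of 5 higher and 0 lower, median 0.24, camera adjusted p = 0.428 in mTEC-IV. Keratin genes had 9 of 20 higher and 3 lower, median 0.50, camera adjusted p = 0.0033, and adjusted p = 0.160 with an estimated correlation in mTEC-III, 4 higher and 10 lower in mTEC-I, 3 higher and 4 lower in mTEC-II and 7 higher and 8 lower in mTEC-IV (camera adjusted p = 0.0870, 0.629 and 0.473 for the last 3). Claudin genes had 1 higher and 3 lower, 1 higher and 2 lower, 4 higher and 3 lower and 6 higher and 2 lower in mTEC-I to mTEC-IV (0.350, 0.530, 0.443 and 0.833).

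The deposited mTEC-I list was the shortest, 7036 peaks against 19321 or more. It also began at a higher signal: at or above its floor of 142.7 the merged table held 9420 peaks in mTEC-I and at most 9273 in another population, a ratio of 0.984. This ratio cannot decide whether the floor made the list short. The floor is the lowest signal of the short list itself. All libraries are scaled to the same total with similar shares of tags in peaks, so similar numbers of strong peaks are likely in any case. A lack of H3K4me2 in mTEC-I at the regions its list leaves out could not be decided either. Of the 9082 peaks listed for the other 3 populations but not mTEC-I, 18.1% were called lower in mTEC-I, between the bounds set for either answer. Their median change was -0.011, with 1642 called lower and 833 higher. Over all tested peaks 6814 of 29469 were called lower in mTEC-I, a larger share. Of the 6747 peaks listed for all 4 populations 257 were (3.81%). The 18.1% thus lies below the share of the whole table and above that of peaks listed for all 4. Neither is a like set: the table also holds peaks listed for fewer populations, and peaks listed for all 4 had to pass the mTEC-I floor. Whether lower calls are in excess therefore cannot be decided. Why the floors differ was not tested, and a biological difference at part of these regions stays open.

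Interferon genes were higher in mTEC-I, 16 of 19 with all 19 changes above 0. The shallow mTEC-I replicate 2 is argued against as the cause, because the list median was 0.48 without it. A trend with mean signal is also argued against: the median of 0.42 lay above that of all 10000 random lists matched on level, at percentile 100, whose highest was 0.38. Fibroblasts in the sort could not be told apart, since of 13 measured fibroblast genes 6 lay under 100 tags per 10000000 in the other populations and 66.7% of these were called higher, with a median of 1.05 over members from -1.10 to 2.15. The Epcam-positive gate is meant to exclude fibroblasts, but the purity of the sort was not tested. A difference between the mTEC populations, or fibroblast genes used by mTEC-I itself, may also be the source and stays untested.

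Ptprc was higher in mTEC-IV although the gate excludes CD45-positive cells, which blood cells in the sort could explain. Myeloid or dendritic cells as the whole source are argued against, as the median of their 5 genes under 100 tags per 10000000 in the other populations was -0.74, with Itgax at -1.60 and Itgam at -0.93, although Flt3 (0.68) and Mpeg1 (0.91) were higher. The Itgax change is against a mean that holds mTEC-III, where it was high, but its level was lowest in mTEC-IV, at 10.4 against 18.1, 25.4 and 84.7. B cells could not be told apart, since Cd79a, Cd79b and Pax5 were all higher with a median of 1.76, but 3 genes are too few and Pax5 was as high in mTEC-II. Thymocytes could not be told apart either, with Cd2 at -0.80, Cd6 at -0.036 and Themis at 1.79, a median of -0.036. H3K4me2 at Ptprc in mTEC-IV cells themselves stays open and was not tested.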
